A study of Drosophila melanogaster with 36 samples.

How the data were processed

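Total RNA from Drosophila melanogaster embryos was measured on NimbleGen 2-colour expression arrays. The embryos came from mothers of 3 genotypes mated to wild-type males and were collected at 0-2 h or 2-4 h, which gives 6 groups. The series has 18 RNA samples, 3 biological replicates per group, and each was hybridised on 2 arrays, giving 36 arrays, 6 per group. Per the labels' protocols, the sample was labelled with Cy5 on every array and a common reference, an equimolar mix of all 18 samples, with Cy3, so no dyes were swapped and a dye effect does not cancel within a group but is shared by the groups compared.

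The authors deposited 1 scanner file per array with the intensity of every probe in both channels on a linear scale. Per the file headers, these intensities were extracted with NimbleScan version 2.5.26 in 35 of the 36 files, and the remaining file carries no software line. Each file holds 137099 probes, of which 4100 are random control probes and 132999 target 16637 transcripts. Of these transcripts, 16617 have 8 probes and 20 have fewer. The deposited value table of the series holds log2 ratios for 137096 probes; the authors' processing of it is not given in the sources used here beyond limma, which the submitters' processing notes name without a version. Set against the scanner files, its columns ran in the direction of Cy5 over Cy3, with column medians between -0.05 and 0.08 and a correlation with the loess-normalized log ratios between 0.919 and 0.979 across probes. Its normalization stays unknown, so it served only as an alternative.

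From the scanner files, background was corrected by normexp with an offset of 50 in limma 3.58.1 under R 4.3.3, and log2(Cy5/Cy3) was normalized by loess within each array, with the random probes at weight 0. The value of a transcript was the median of its probes. The titles number the arrays of a group 1 to 6 without stating which share an RNA sample. Array n was taken with array n+3, since arrays 1 to 3 of a group lie on one slide and 4 to 6 on another, and the pairs were averaged before any test. This pairing was checked: for 36 of 36 arrays, the partner so assigned had the highest correlation of deviations from the group mean within the group. Group means were fitted to the 18 averaged samples with lmFit and eBayes of limma, and a transcript was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values in the text come from this moderated test, two-sided, over 16637 transcripts, unless another setting is named. The tests cover 3 stage comparisons, 6 genotype comparisons and 2 interactions. Single values per sample, such as class medians, were compared by a two-sided exact permutation test, which for 3 samples against 3 cannot give a p below 0.1.

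A transcript was counted as detected on an array when its Cy5 signal exceeded the 95th percentile of the random probes of that array. Medians of 8 random probes passed that level in at most 0.05% of draws on any array. Between 6490 and 8102 transcripts were detected per array, or 39.0% to 48.7%, and the median probe was 2.29 to 3.06 times the median random probe in Cy5. The number of arrays limits the precision. Where a named transcript was not above the random probes on any array of a group, only a bound is given, computed per channel after loess and Aquantile as the brighter group's mean over the dimmer group's mean of the higher of that detection level and its own signal; with no dye swap, such bounds are open to dye bias.

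3 classes of transcripts were defined from wild type alone. The falling class fell at least 2-fold with an adjusted p under 0.05 and was detected on all 6 arrays of wild type at 0-2 h. The rising class rose at least 2-fold by the same test and was detected on all 6 arrays at 2-4 h. The newly detected class was detected on 0 arrays of wild type at 0-2 h and on all 6 at 2-4 h. Selection on wild type inflates the wild-type change, so the classes were also chosen with one replicate number of wild type left out and measured in the samples left out.

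The pipeline was tested on simulated data for aub against wild type at 2-4 h over 16637 transcripts, 50 of them changed at each of 4 sizes. It recovered 40 of 50 at a log2 change of 0.5 and 50 of 50 at 1, at 2 and at -1. Of the 196 calls, 6 were unchanged transcripts, or 3.06%. Almost all simulated transcripts were unchanged, as loess assumes, whereas the real comparison called 6841 of 16637. The recovery and the share of false calls therefore do not carry over to comparisons with such widespread change. Estimates were compressed: a true log2 change of 1 had a median estimate of 0.86, or 0.99 among those above the median intensity. Folds of dim transcripts are therefore understated.

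The arrays lie on 3 slides of 12, and each slide holds 4 of the 6 groups, so slide was tested as a block and within each slide that holds both groups compared. In 2 aub arrays the file header names another slide than the file. Both correlated best with their assigned partners, at 0.937 and 0.922, against at most 0.732 and 0.419 with arrays of other groups, and were kept. The lowest correlation between any 2 arrays was -0.62. The dyes are stated by the labels and the reference is a mix of all groups, so that early and late samples can lie on opposite sides of it, and the direction was kept.

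Replicate numbers come from the array titles. Whether they pair samples across groups was checked from the correlation of same-numbered samples' deviations from their group means. Over the transcripts above the median intensity all 3 pairs lay above 0.1 between the stages of aub (lowest 0.407), between the stages of spn-E (lowest 0.164) and between aub and wild type at 2-4 h (lowest 0.109). Over all transcripts this held between the stages of aub alone among the comparisons made (lowest 0.262). The first of these was examined first, before calls were compared, and both are given because they differ.

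The files name transcripts by FlyBase transcript number and do not pair them with genes. The gene table used here lists 43 of the 16637 transcripts under gene symbols: 16 under 1 gene, and 27 as messages that hold the open reading frames of several genes, written here as "X with Y". 1 more is listed under several main genes and was left unnamed. As a result, the 29 gene lists fixed beforehand could not be tested, since no list matched more than 1 of these transcripts against a minimum of 4, and the transcripts of aub and spn-E themselves were not analysed here. The named transcripts of each comparison are the 5 largest rises and 5 largest falls among those called whose 3 samples of one group all lie above or below the 3 of the other, which chance gives to 10% of transcripts, and whose first symbol is more than an annotation number, plus the single largest rise and fall of all transcripts. For interactions the condition on overlap is dropped. At most 4 unnamed transcripts are identified by number.

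The choices above, except where stated, and the alternatives were fixed before the data were examined: no background correction, no loess, a further quantile step, Cy5 alone, the value table, the mean of the probes, a filter on dim transcripts, slide and replicate number as blocks, other ways of combining the arrays, an intensity trend, only the groups compared, a 2-fold minimum, and each RNA sample left out in turn. Without loess, the log ratios of each array were centred on their median, and Cy5 alone was quantile-normalized across arrays. The classes, the stricter detection level, a 4-fold class and the run without the 2 aub arrays were chosen after the data had been seen.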

Results

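The series measured maternal and early zygotic RNA in Drosophila embryos whose mothers carried mutations in aubergine (aub) or spindle-E (spn-E). Both genes act in the piRNA pathway of the germline: aub encodes an Argonaute protein of the Piwi family and spn-E a helicase with a Tudor domain. Wild-type (w1118), aub and spn-E embryos were collected at 0-2 h, when RNA laid down by the mother makes up most of the pool, and at 2-4 h, when wild-type embryos have degraded many maternal messages and begun to transcribe their own genome. Each of the 6 groups held 3 RNA samples measured on 2 arrays each. The design asks how this turnover differs when the mother carries either mutation. In a principal component analysis of the 18 samples, the first component held 67.1% of the variance and the second 17.1%.

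Wild-type embryos changed a large part of their transcript pool between the stages. Of the named transcripts, rdx, an adaptor of a Cullin-3 ubiquitin ligase, fell 5.43-fold (log2 -2.44, SE 0.17, adjusted p = 9.47e-10), and Uba1, the ubiquitin-activating enzyme, fell 3.19-fold (log2 -1.68, SE 0.11). The message of PIG-P with Tcs6 fell 3.32-fold, the nucleolar protein gene sle 3.18-fold and the phosphate transporter gene NaPi-III 2.81-fold. LanA, a laminin alpha chain, was above the random probes on 1 of 6 arrays at 0-2 h and 6 of 6 at 2-4 h, so its rise is given without a size. Other rises were those of alpha-Spec, the alpha subunit of spectrin (2.75-fold, SE 0.14), Mocs2B with Mocs2A, the molybdopterin synthase subunits (2.32-fold), mio, a component of the GATOR complex (2.05-fold), and lmgB with lmgA (1.74-fold). Among unnamed transcripts, FBtr0086268 rose 33.7-fold and FBtr0070749 fell 140-fold.

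In the limma fit, 7483 of 16637 transcripts (45.0%) differed between the stages of wild type, 3761 higher and 3722 lower at 2-4 h (3539 and 3651 without loess), and 2761 differed by at least 2-fold, 1041 higher and 1720 lower. Loess centres the log ratios of each array, so the split between higher and lower calls depends on it, here and in the comparisons below. An even split therefore does not show that as many transcripts rose as fell. Of the 43 named transcripts, 16 rose, 16 fell and 11 did not pass the test. The count was 7652 with slide as a block, 6847 within the first slide and 6882 within the second. The falling class held 1699 transcripts with a median log2 change of -1.57, and the rising class 936 with a median of 1.47. Measured in wild-type samples left out of the selection, the medians were -1.52, -1.53 and -1.77 for falling transcripts and 1.43, 1.40 and 1.54 for rising ones.

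In aub embryos, most transcripts that fell in wild type also fell, and the median change was smaller than in wild type for falling and rising transcripts alike. The rdx message fell 5.05-fold (log2 -2.34, SE 0.17), sle 3.32-fold, Uba1 by a log2 change of -1.59 and PIG-P with Tcs6 2.63-fold. The message of Tim10, a mitochondrial import chaperone, with CG42497 fell 2.48-fold (SE 0.15, adjusted p = 1.85e-06). The named rises were small, at 1.53-fold for alpha-Spec, 1.48-fold for Gint3 with CG42306, 1.47-fold for mio, 1.45-fold for lmgB with lmgA and 1.43-fold for the histone deacetylase gene HDAC3. The class that fell in wild type had a median log2 change of -1.03 in aub, with 1379 of 1699 members (81.2%) called lower, whereas the class that rose had a median of 0.43, with 573 of 936 (61.2%) called higher and 80 by at least 2-fold.

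Across all transcripts, 5835 differed between the stages of aub, 2936 higher and 2899 lower, and 1387 differed by at least 2-fold, of which 81 were higher and 1306 lower. Of the named transcripts, 11 rose and 18 fell. The count was 6208 with slide as a block, 5020 within the first slide and 6054 within the third. Without loess, 4468 transcripts were called, 1447 higher and 3021 lower, and none of the 5 named rises passed the test: HDAC3 and Gint3 stood at a log2 change of 0.37 and 0.35, alpha-Spec and lmgB at 0.34 and 0.18.

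In spn-E embryos the changes between the stages were small in size. The named falls were sle (1.61-fold, log2 -0.68, SE 0.11, adjusted p = 0.00150), Uba1 (1.57-fold), rdx (1.48-fold), Wdr24 (1.40-fold) and Rad1 with Sws1 (1.36-fold), and the named rises were HDAC3 (1.30-fold), Ppcdc with CG42496 (1.27-fold), Tcs1 with Polr3K (1.21-fold), Mettl5 with CG42374 (1.19-fold) and Gint3 with CG42306 (1.17-fold). The class that fell in wild type had a median log2 change of -0.38, with 846 of 1699 members (49.8%) called lower and 13 by at least 2-fold. The class that rose in wild type had a median of 0.10, with 116 of 936 (12.4%) called higher and 1 by at least 2-fold.

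In all, 2483 transcripts differed between the stages of spn-E, 958 higher and 1525 lower, and 18 differed by at least 2-fold, 1 higher and 17 lower. Of the named transcripts, 7 rose and 9 fell. The count was 3465 with slide as a block, 1505 within the second slide and 2419 within the third. The number of higher transcripts changed with the normalization, with 50 higher and 1683 lower without loess, 301 and 1007 with Cy5 alone, and 143 and 1614 in the deposited value table, and the named rises did not pass the test under any of these 3. Without loess, with Cy5 alone and in the value table, the log2 change of HDAC3 was 0.25, 0.31 and 0.31, that of Ppcdc 0.29, 0.33 and 0.36 and that of Gint3 0.11, 0.18 and 0.16. The count was 923 without spn-E replicate 1 at 2-4 h and 1283 without replicate 2 at 0-2 h, and of the 5 named falls those of rdx and of Rad1 with Sws1 did not pass the test without single spn-E samples, nor did the named rises except that of Ppcdc. The fall of rdx also did not pass without loess (log2 -0.60), with Cy5 alone (-0.29) or in the value table (-0.54), nor that of Rad1 with Cy5 alone (-0.46). With replicate number as a block, the rises of Tcs1 (adjusted p = 0.0611) and Gint3 (0.0598) did not pass.

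**Figure D1:**
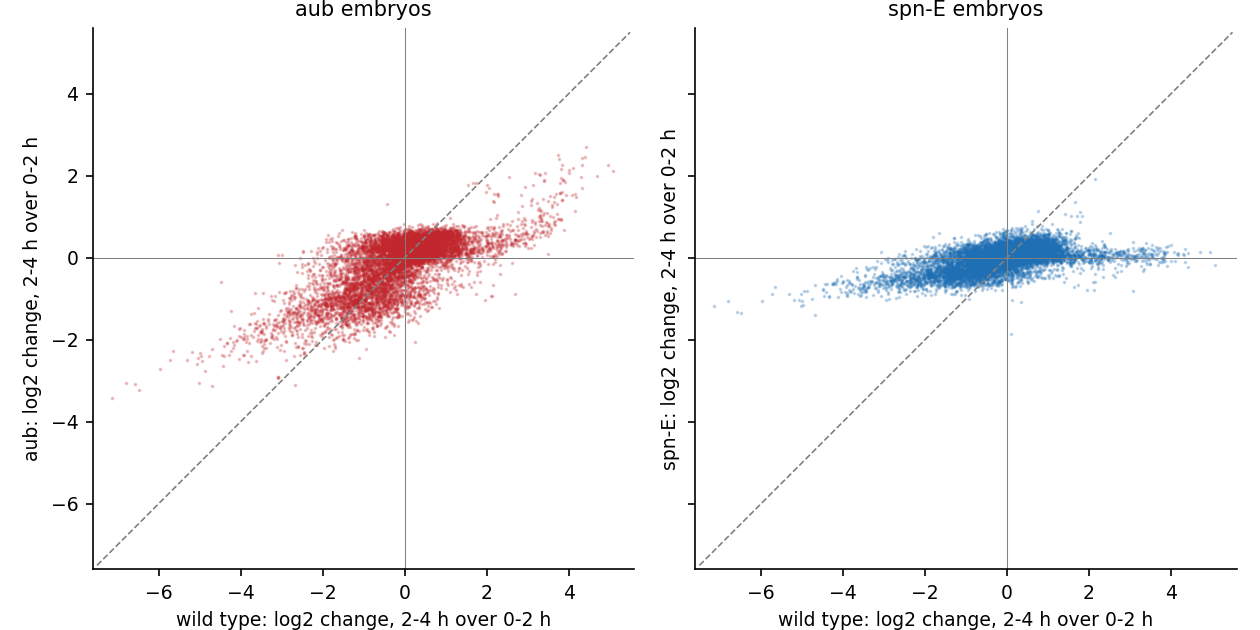
Each point is 1 of 16637 transcripts, with its log2 change from 0-2 h to 2-4 h in wild type on the horizontal axis and in aub (left) or spn-E (right) on the vertical axis; the dashed line marks equal change. The slope of the mutant change on the wild-type change was 0.424 in aub and 0.144 in spn-E.

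The genotypes differed less at 0-2 h than at 2-4 h in the number of transcripts called. Against wild type at 0-2 h, aub embryos had less of the Uba1 message (1.36-fold lower, log2 -0.45, SE 0.11, adjusted p = 0.0150) and of Wdr24 (1.30-fold lower), and more of ND-MNLL with CG45089 (1.24-fold higher, adjusted p = 0.0393), a subunit of mitochondrial complex I. The unnamed transcript FBtr0077914 was 21.1-fold lower, and above the random probes on 4 of 6 aub arrays. The largest rise, of another unnamed transcript, was 14.9-fold, with a log2 SD of 1.32 in wild type, where 5 of 6 arrays detected it. In all, 1865 transcripts differed, 856 higher and 1009 lower in aub, and 259 by at least 2-fold. The split turned to 699 higher and 614 lower without loess and to 812 and 782 in the value table. The count was 2464 with slide as a block and 1145 within the single slide that holds both groups. Of the named transcripts, 3 were higher and 4 lower, and Uba1 and Wdr24 did not pass the test without loess, at log2 -0.24 and -0.23, or in the value table, at -0.34 and -0.33. ND-MNLL did not pass without background correction (0.31). The calls of Uba1, Wdr24 and ND-MNLL no longer passed when single samples were left out.

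By 2-4 h, aub embryos had less of most transcripts that rose in wild type and more of most that fell. LanA was at least 2.46-fold lower than in wild type (adjusted p = 4.52e-08), being above the random probes on 0 of 6 aub arrays and 6 of 6 wild-type arrays. The alpha-Spec message was 2.23-fold lower (log2 -1.16, SE 0.14), Tgs1, the cap trimethylase, with moi 2.21-fold lower (SE 0.09), the mevalonate kinase gene Mvk with CG33672 1.73-fold lower and Mocs2B with Mocs2A 1.61-fold lower. The largest named excesses were modest: Gint3 with CG42306 was 1.44-fold higher, fend 1.39-fold, SuUR 1.38-fold, ND-MNLL with CG45089 1.36-fold and vnc with CG42455 1.35-fold. None of these was among the 5 largest named falls of wild type. Of those falls, rdx had a mean log2 ratio of -2.06 in aub against -2.41 in wild type, and PIG-P -1.11 against -1.49. Uba1 and sle went the other way, at -1.54 against -1.18 and -1.47 against -1.26. FBtr0070749, which fell most in wild type, was 15.8-fold higher in aub, and FBtr0086268, which rose most, 88.2-fold lower. The mean log2 ratio of FBtr0086268 in aub at 2-4 h, -2.95, lay below that of wild type at 0-2 h, -1.56. A missing rise alone therefore does not give the size of its difference.

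For this comparison 6841 transcripts were called, 3437 higher and 3404 lower in aub (2925 and 2964 without loess, 3213 and 3615 in the value table), and 1993 differed by at least 2-fold, 947 higher and 1046 lower. Of the falling class, 1181 of 1699 members (69.5%) were higher in aub and 120 lower. Of the rising class, 863 of 936 (92.2%) were lower and 2 higher, and of the 224 newly detected transcripts 223 were lower. The count was 6932 with slide as a block and 5972 within the single slide that holds both groups. Of the named transcripts, 11 were higher and 17 lower, and fend did not pass the test with Cy5 alone (log2 0.32) or without single samples, nor Mocs2B with only these groups in the fit (adjusted p = 0.0562).

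Against wild type at 0-2 h, spn-E embryos had less of Pbp49 with CG42516 (1.47-fold lower, log2 -0.56, SE 0.07, adjusted p = 2.83e-05), HDAC3 (1.23-fold lower) and Tcs1 with Polr3K (1.22-fold lower), and no named transcript was called higher. The transcript FBtr0077914 was at least 17.8-fold lower in spn-E, where it was above the random probes on 0 of 6 arrays. The largest rise, of another unnamed transcript, was at least 28.5-fold. It was above the random probes on 6 of 6 spn-E arrays and 0 of 6 wild-type arrays. In all, 1533 transcripts differed, 681 higher and 852 lower, and 263 by at least 2-fold. The count was 2173 with slide as a block and 1058 within the single slide that holds both groups. The split turned to 1003 higher and 598 lower without loess, 582 and 516 with Cy5 alone and 675 and 623 in the value table. Without loess none of the 3 named calls passed the test, with Pbp49 at log2 -0.30, HDAC3 at -0.10 and Tcs1 at -0.11. Nor did HDAC3 and Tcs1 with Cy5 alone (both -0.12) or in the value table (-0.25 and -0.27). The count was 988 without spn-E replicate 3, and the calls of HDAC3 and Tcs1 did not pass the test without single samples.

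By 2-4 h, spn-E embryos had more of the messages that fell in wild type and less of those that rose. The rdx message was 5.35-fold higher than in wild type (log2 2.42, SE 0.17, adjusted p = 1.12e-09), PIG-P with Tcs6 3.47-fold, Uba1 2.21-fold, sle 2.14-fold and NaPi-III 1.97-fold higher. LanA was at least 2.56-fold lower (above the random probes on 0 of 6 spn-E arrays), alpha-Spec 2.95-fold lower (log2 -1.56, SE 0.14), mio 2.16-fold, Mocs2B with Mocs2A 1.90-fold and lmgB with lmgA 1.72-fold lower. Among unnamed transcripts, FBtr0082607 was 148-fold higher and FBtr0086268 625-fold lower. For FBtr0086268 the log2 difference at 2-4 h was -9.29, while its change with stage differed from that in wild type by -5.26. Part of the difference was therefore already present at 0-2 h.

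The test called 7562 transcripts between spn-E and wild type at 2-4 h, 4020 higher and 3542 lower (3444 and 3585 with Cy5 alone, 3680 and 4366 in the value table), and 2693 differed by at least 2-fold, 1602 higher and 1091 lower. Of the falling class, 1679 of 1699 members (98.8%) were higher in spn-E and 2 lower, and of the rising class 908 of 936 (97.0%) were lower and 2 higher. All 224 newly detected transcripts were lower. The count was 7588 with slide as a block and 6846 within the single slide that holds both groups. Of the named transcripts, 17 were higher and 14 lower.

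For the falling class the mean of the sample medians of log2(Cy5/Cy3) went from 0.34 ± 0.02 (SD, n = 3) at 0-2 h to -1.33 ± 0.11 at 2-4 h in wild type, from 0.20 ± 0.07 to -0.82 ± 0.15 in aub, and from 0.40 ± 0.03 to 0.04 ± 0.09 in spn-E. For the rising class it went from -0.43 ± 0.02 to 1.18 ± 0.05 in wild type, from -0.49 ± 0.03 to -0.23 ± 0.02 in aub, and from -0.60 ± 0.02 to -0.48 ± 0.06 in spn-E. At 2-4 h the 3 samples of each genotype did not overlap those of another in either class, and each exact permutation test gave its smallest possible p of 0.1. The same held at 0-2 h, except for the falling class in spn-E against wild type (permutation p = 0.2). In the rising class the differences from wild type were smaller at 0-2 h, -0.06 in aub and -0.18 in spn-E, than at 2-4 h, -1.40 and -1.65.

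**Figure D2:**
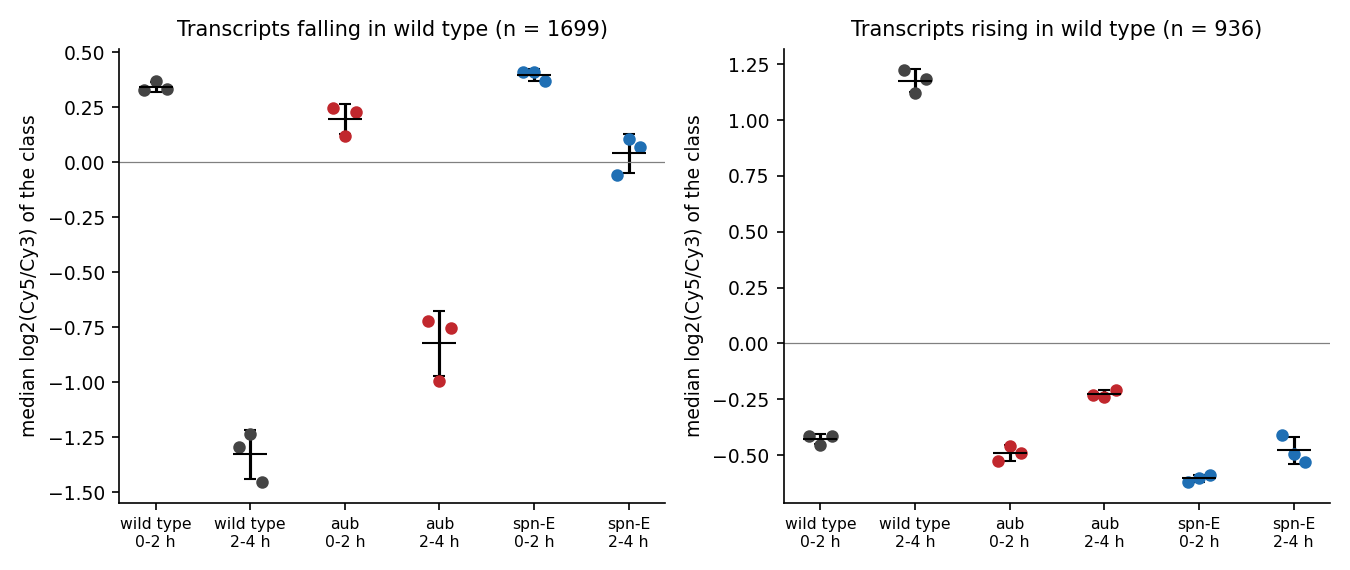
Each point is the median log2(Cy5/Cy3) over the 1699 transcripts that fell (left) or the 936 that rose (right) in wild type, for 1 of 3 RNA samples per group; horizontal bars are group means and error bars the SD. At 2-4 h the falling class lies at -1.33 in wild type, -0.82 in aub and 0.04 in spn-E, and the rising class at 1.18, -0.23 and -0.48.

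Compared directly at 0-2 h, spn-E embryos had more of the Uba1 message than aub embryos (1.48-fold, log2 0.57, SE 0.11, adjusted p = 0.00375) and of Wdr24 (1.31-fold), and less of Pbp49 with CG42516 (1.56-fold lower), Mvk with CG33672 (1.36-fold lower) and HDAC3 (1.29-fold lower). In all, 1555 transcripts differed, 895 higher and 660 lower in spn-E, and 162 by at least 2-fold. The count was 2279 with slide as a block and 1530 within the single slide that holds both groups. Without loess it was 920, with 672 higher and 248 lower, and it was 815 without aub replicate 2 and 917 and 1003 without spn-E replicates 2 and 3. The calls of Wdr24, Mvk and HDAC3 did not pass without single samples. Mvk and HDAC3 also did not pass without loess (log2 -0.39 and -0.33), with Cy5 alone (-0.48 and -0.29) or in the value table (-0.47 and -0.40), nor Wdr24 in the value table (0.39).

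At 2-4 h, spn-E embryos had more than aub embryos of most messages that fell in wild type. The rdx message was 4.23-fold higher in spn-E (log2 2.08, SE 0.17, adjusted p = 5.18e-08), Uba1 2.83-fold, PIG-P with Tcs6 2.65-fold, sle 2.47-fold and Tim10 with CG42497 2.41-fold higher. Lower in spn-E were lmgB with lmgA (1.73-fold), Pbp49 with CG42516 (1.59-fold), fend (1.47-fold), HDAC3 (1.42-fold) and Gint3 with CG42306 (1.40-fold). Of 5539 transcripts called, 3030 were higher and 2509 lower in spn-E, and of 1186 that differed by at least 2-fold, 1011 were higher and 175 lower. Members of the falling class were higher in spn-E in 1353 of 1699 cases (79.6%) and lower in 80. The count was 5832 with slide as a block and 5737 within the single slide that holds both groups. The split was 2972 higher and 1426 lower without loess and 2538 and 2626 with Cy5 alone. Without loess fend (log2 -0.60), HDAC3 (-0.44) and Gint3 (-0.33) did not pass the test, nor did fend without replicate 3 of aub (-0.46) or of spn-E (-0.36) at 2-4 h.

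The change with stage was then compared between each mutant and wild type within one fit. In aub, the rise of alpha-Spec fell short of that in wild type by a log2 difference of -0.85, and the change was lower in aub for Mvk with CG33672 (-1.06), Tgs1 with moi (-1.05) and Tim10 with CG42497 (-0.95). It was higher in aub for SuUR (0.43), Gint3 with CG42306 (0.35), Pbp49 with CG42516 (0.34) and Tcs1 with Polr3K (0.34). Without loess these 4 and Tim10 did not pass the test, SuUR at 0.52 (adjusted p = 0.0795), Tcs1 at 0.38 (0.0516), Tim10 at -1.14 (0.0614), Gint3 at 0.22 and Pbp49 at 0.14. With Cy5 alone Tim10 (-0.53), Gint3 (0.08), Pbp49 (0.24) and Tcs1 (0.49) did not pass, and in the value table Gint3 (0.28) and Pbp49 (0.18). None of the 4 higher changes passed within the first slide alone, SuUR at 0.37, Gint3 at 0.22, Pbp49 at 0.31 and Tcs1 at 0.36. Tcs1 also did not pass with only these groups in the fit (adjusted p = 0.0595), with the replicate block (0.0629) or without single samples (log2 0.23 without wild-type replicate 3 at 2-4 h). The interaction called 4921 transcripts, 2464 higher and 2457 lower (1800 and 1958 without loess, 2235 and 2491 in the value table), and 5455 with slide as a block and 4115 within the single slide that holds all 4 groups. It was higher in 1186 of the 1699 members of the falling class and lower in 871 of the 936 of the rising class. In 20 simulations in which the mutants changed exactly as wild type, no member of either class was called in that direction. With no interaction present the adjusted test calls almost nothing, so these simulations decide nothing about the counts above.

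In spn-E the change with stage was higher than in wild type for rdx (log2 difference 1.87, SE 0.24, adjusted p = 5.63e-06), PIG-P with Tcs6 (1.38), NaPi-III (1.21), Uba1 (1.02) and sle (0.99). It was lower for alpha-Spec (-1.37), Mocs2B with Mocs2A (-0.95), mio (-0.95) and lmgB with lmgA (-0.68; -0.51 without loess, where it did not pass the test). The interaction called 5473 transcripts, 3008 higher and 2465 lower (2422 and 2586 with Cy5 alone, 2749 and 2984 in the value table), with 5962 with slide as a block and 4857 within the single slide that holds all 4 groups. It was higher in 1656 of 1699 members of the falling class and lower in 909 of 936 of the rising class.

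**Figure D3:**
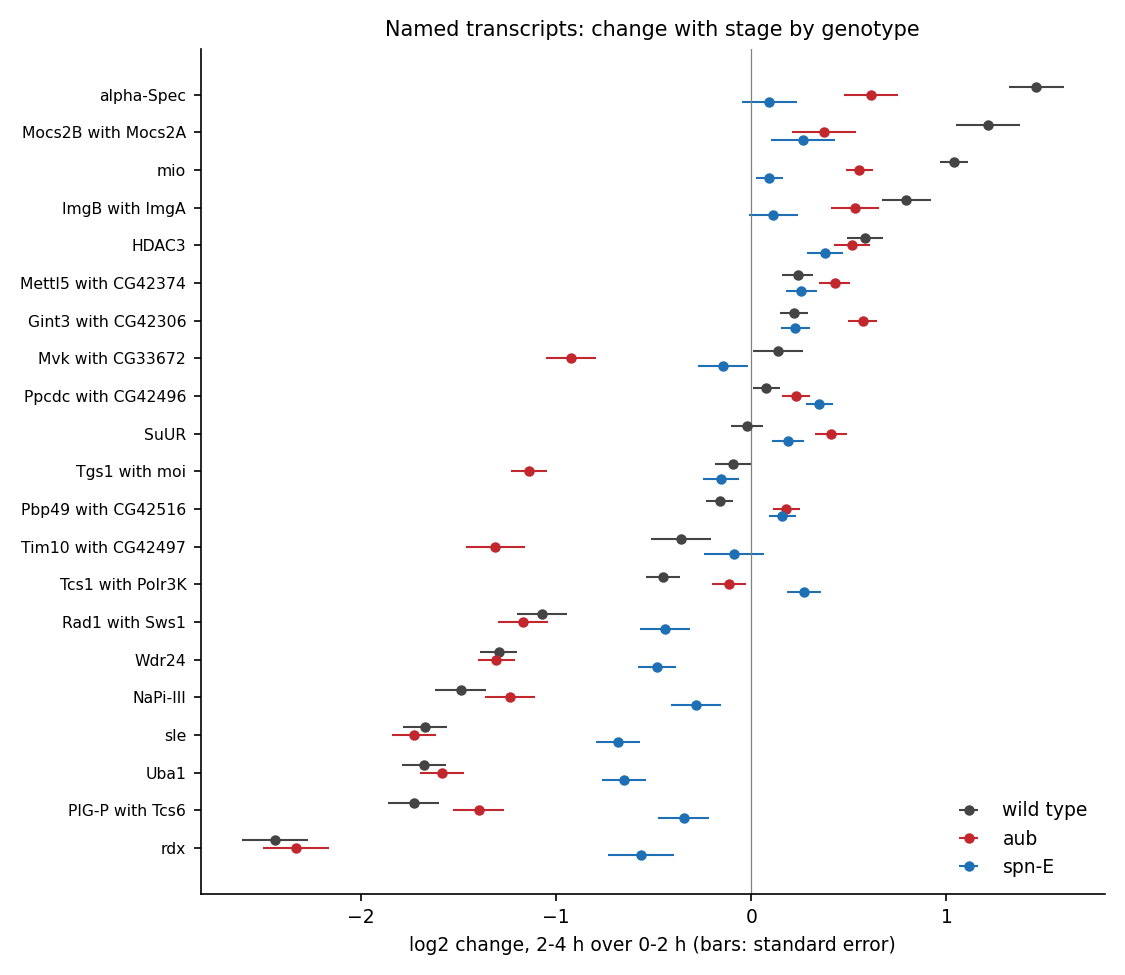
Log2 change from 0-2 h to 2-4 h (horizontal axis) of the named transcripts above the random probes in each genotype (vertical axis) in wild type, aub and spn-E; points are fitted changes over 3 RNA samples per group and bars the standard error. The rdx point lies at -2.44 in wild type, -2.34 in aub and -0.57 in spn-E.

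Many transcripts differed from wild type in the same direction in both mutants. Across transcripts, which are not independent replicates, the log2 differences of aub and spn-E from wild type correlated at 0.674 at 0-2 h and 0.841 at 2-4 h. Both comparisons share the wild-type samples, and unchanged groups simulated against such samples gave 0.501 and 0.502. The covariance was 0.0760 against a simulated 0.00651 at 0-2 h and 0.585 against 0.00651 at 2-4 h, a difference of 0.0695 and 0.578. At 0-2 h, 264 transcripts were higher and 441 lower in both, where independent lists would share 35.0 and 51.7 and the simulations 0 and 0. At 2-4 h, 2545 were higher and 2497 lower in both, where independent lists would share 830.5 and 724.7 and the simulations 0 and 0, and 403 went opposite ways. The simulated groups held no change, so the test calls almost nothing in them. Their shared counts of 0 therefore decide nothing about the overlap. The highest simulated correlations were 0.517 at 0-2 h and 0.520 at 2-4 h. With the covariances, they argue against replicate error in the shared wild-type samples as the source of the excess. The 3 wild-type samples per stage are too few to split with at least 2 on each side, so the overlap was not tested with separate controls. A deviation common to all wild-type samples of a stage would also be shared and was not tested.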

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

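The test of a shared fraction of clearance and rise in aub was chosen after the result was seen, and the other tests in this part before. The change with stage differed from wild type for 4921 transcripts in aub and 5473 in spn-E by the interaction test. Its median was 0.84 in aub and 1.35 in spn-E over the falling class, and -1.22 and -1.39 over the rising class. Among 100 regroupings of genotype within stage, the real one included, 6 gave as many calls for aub and 10 for spn-E, with the highest other at 6213 and 6202, so this test does not exclude chance. All of those regroupings kept the groups at 2-4 h whole and so carried the genotype difference at that stage. Those groups stayed whole in 8 regroupings for aub and 11 for spn-E. Regroupings that split them reached at most 98 calls for aub and 55 for spn-E.

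The named interactions were, in aub, SuUR at 0.43, Gint3 with CG42306 at 0.35, Pbp49 with CG42516 at 0.34, Tcs1 with Polr3K at 0.34, LanA at -1.43, Mvk with CG33672 at -1.06, Tgs1 with moi at -1.05, Tim10 with CG42497 at -0.95 and alpha-Spec at -0.85. In spn-E they were rdx at 1.87, PIG-P with Tcs6 at 1.38, NaPi-III at 1.21, Uba1 at 1.02, sle at 0.99, LanA at -1.90, alpha-Spec at -1.37, Mocs2B with Mocs2A at -0.95, mio at -0.95 and lmgB with lmgA at -0.68. The values of LanA give no size or direction, since it was above the random probes on 0 of 6 arrays of either mutant at both stages and on 1 of 6 wild-type arrays at 0-2 h. The largest interactions of unnamed transcripts were 3.89 and -3.58 in aub, the latter without a firm size because the transcript was above the random probes on no wild-type array at 0-2 h and no aub array at 2-4 h, and 5.97 for FBtr0070749 and -5.26 for FBtr0086268 in spn-E. The effects of the 2 mutations themselves differed for 1555 transcripts at 0-2 h and 5539 at 2-4 h, by the test of spn-E against aub.

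For the 9 comparisons of 3 samples against 3, the 10 possible splits are too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many calls. The real counts and the highest other were 7483 and 2 for the stages of wild type, 5835 and 0 for aub, 2483 and 0 for spn-E, 1865 and 0 for aub against wild type at 0-2 h, 6841 and 0 at 2-4 h, 1533 and 1 for spn-E against wild type at 0-2 h, 7562 and 0 at 2-4 h, 1555 and 0 for spn-E against aub at 0-2 h, and 5539 and 0 at 2-4 h. In 36 tests for a lone extreme array among 6, on 6 measures in 6 groups, 1 array stood apart: aub at 2-4 h array 3, with a Cy5 signal 2.46 times the random probes against 2.29 to 2.34 on the other arrays. Chance marks about 1 in 20 groups. Groups of 3 RNA samples were not tested this way.

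The first pattern weighed is the rise of the rising class, which stayed small in both mutants. Of its 936 members, 590 were detected on all 6 wild-type arrays at 0-2 h and 217 on none. A rise in this class is therefore not by itself shown to be zygotic. Loess itself was argued against, since without it or with Cy5 alone the rising class kept at least 0.935 of its median difference from wild type at 2-4 h. These settings centred each array on its median or gave all arrays the same distribution. An effect of scaling between arrays was therefore not tested. The slide was argued against, since within the single slide that holds both genotypes at least 0.957 remained. A mixture was weighed in which some mutant embryos develop like wild type and the rest stay as at 0-2 h. With equal levels at 0-2 h, it would give a single fraction of the wild-type change, on the linear scale, for every transcript. The interquartile range of the fraction reached was 4.76 times the simulated one in aub and 2.65 times in spn-E. The simulation added only replicate error to normalized values and left out the compression of dim transcripts. Levels at 0-2 h were also unequal, with 286 of the 936 members called lower in aub than in wild type. The wider spread therefore does not decide against such a mixture. A mixture whose other embryos change in some other way was not tested. In aub the median fraction on the linear scale was 62.2% for clearance and 8.97% for the rise. Over left-out samples the ranges stayed 48.5 percentage points apart, against one fraction shared by clearance and rise. The class medians given above are log2 changes and do not yield these fractions: -1.03 in aub against -1.57 in wild type, and 0.43 against 1.47. A delay of development, which need not give one fraction, stays open. An effect of the maternal genotype on zygotic transcription stays open as a hypothesis, and neither the age of the embryos within each window nor the background of the stocks could be tested.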

How the results depend on the processing

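The class definitions, the stricter detection level, the 4-fold class and the run without 2 aub arrays were chosen after seeing the data. No class median or named value changed sign under any alternative, but the side with more calls turned without loess, with Cy5 alone or in the value table in all comparisons except the stages of spn-E and spn-E against aub at 0-2 h. Of the values of named transcripts, 2639 kept their side of the threshold while 217 no longer passed. The signal over random probes, 2.29 to 3.06, limits what dim transcripts can show. Gene lists and the aub and spn-E transcripts were not run. With a 2-fold minimum the counts were 2761, 1387 and 18 for the stages of wild type, aub and spn-E, 259 and 1993 for aub against wild type at 0-2 h and 2-4 h, 263 and 2693 for spn-E against wild type, 162 and 1186 for spn-E against aub, and 1710 and 2202 for the interactions. Averaging arrays 1 with 2, 3 with 4 and 5 with 6 gave 4634 for the spn-E stages and 3994, 3697 and 3692 for the genotype comparisons at 0-2 h (aub and spn-E against wild type, spn-E against aub), and 36 arrays taken as independent gave 4282, 3574, 3221 and 3331, since neither averages technical pairs. For the other changes the cause was not tested. The spn-E stage count was 1308 with Cy5 alone, 1505 within the second slide, 1606 with arrays 4 to 6 alone and 3928 with only its groups in the fit. Against wild type at 0-2 h, aub gave 1145 within the first slide. For spn-E against aub at 0-2 h the count was 920 without loess, 1017 with arrays 4 to 6 and 2612 with only these groups. With the replicate block, the count for the stages of aub was 6024 and none of the 11 counts moved by over 1.5 times, while Tcs1 with Polr3K in 3 comparisons and Gint3 with CG42306 in 1 no longer passed; with the replicate block and slide together, spn-E against wild type at 0-2 h gave 2374 and spn-E against aub 2487.

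The falling class median was -1.81 without background correction, -1.74 without loess and -1.87 in the value table in wild type, -1.28 without loess and -1.28 in the value table in aub, and -0.51 and -0.48 in spn-E. In wild type the rising class median was 1.70 without background correction, 1.66 with Cy5 alone, 1.75 in the value table, and 1.53 both within the second slide and with arrays 4 to 6 alone; in aub it was 0.53, 0.34 without loess, 0.49 with Cy5 alone, 0.47 in the value table and 0.50 with the 99th percentile of random probes. In spn-E it ran from 0.05 without loess to 0.14 within the second slide. The 4-fold classes gave -2.60, -1.44 and -0.53 for falls in wild type, aub and spn-E, and 2.76 and 0.59 for rises in wild type and aub. Without loess the correlation of aub and spn-E effects at 0-2 h was 0.721. That setting moved the median log2 change of all transcripts in aub to 0.13, and the value table moved it to 0.15 in aub and 0.10 in wild type. The further quantile step leaves log ratios as they are and so tested nothing.

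Leaving out each RNA sample gave 6998 to 7391, 5069 to 5616 and 923 to 2215 calls for the stages of wild type, aub and spn-E, the lowest without spn-E replicate 1 at 2-4 h, and 1283 without replicate 2 at 0-2 h. Counts ran 1336 to 1480 and 6315 to 6752 for aub against wild type at the 2 stages, 988 (without spn-E replicate 3) to 1217 and 7007 to 7455 for spn-E against wild type, 815 to 1281 and 4808 to 5391 for spn-E against aub (815 without aub replicate 2, and 917 and 1003 without spn-E replicates 2 and 3), and 4539 to 5081 and 5063 to 5551 for the interactions. Class medians ran -1.62 to -1.51, -1.08 to -0.95 and -0.41 to -0.32 for falls in wild type, aub and spn-E, and 1.47 to 1.52, 0.41 to 0.46 and 0.07 to 0.13 for rises. The correlations ran 0.643 to 0.702 and 0.823 to 0.861.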

Other observations

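The test on replicates left out of the choice was chosen after the ratio of the full sets was seen, and the other tests in this part before their results, but the sets they run on were noticed in these data. A set of transcripts fell in aub embryos without falling in wild type. Of 338 that fell at least 2-fold in aub with a lower change than in wild type by the interaction test, 202 were also called lower in wild type and 136 were not, among them Tgs1 with moi and Tim10 with CG42497, although the interaction of Tim10 did not pass the test without loess (-1.14) or with Cy5 alone (-0.53). The 136 had a median log2 change of -1.19 in aub, -0.03 in wild type and -0.44 in spn-E, where 90 were called lower and 0 higher. At 0-2 h 134 of them were detected on all 6 wild-type arrays.

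Loess does not account for the set as a whole, since 94.1% kept a lower change in aub without it or with Cy5 alone, whichever was fewer. Both settings still equalize the arrays, so scaling between arrays was not tested. A candidate explanation is that wild-type embryos transcribe these genes again while the maternal copies decay in all genotypes, and that aub embryos show the decay alone. Under that hypothesis spn-E embryos would clear the set in the same proportion to aub as other maternal transcripts, and the ratio of median changes, spn-E over aub, was 0.372 here (95% of resamplings of the set between 0.351 and 0.409) against 0.368 in the falling class, a difference of 0.00455. That comparison alone decides nothing, since the set was chosen on its fall in aub and the class was not. The resampling drew transcripts, so its range leaves out the error between RNA samples. With falling transcripts chosen on the same fall, and the aub change measured in a replicate left out of both choices, the ratio was 0.376, 0.398 and 0.377 in the set and 0.372, 0.356 and 0.365 in the falling transcripts, a largest difference of 0.0419. The set was still chosen on its difference from wild type. The explanation stays a hypothesis. Faster decay in the mutants than in wild type was not tested.

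Detection was also counted in the classes, which were chosen on wild type. Of the 224 transcripts above the random probes on 0 wild-type arrays at 0-2 h and on all 6 at 2-4 h, 215 (96.0%) were above them on 0 aub arrays at 2-4 h and 216 (96.4%) on 0 spn-E arrays. Clearance also differed in its end point: 256 of the 1699 falling transcripts (15.1%) were above the random probes on 0 wild-type arrays at 2-4 h, against 90 in aub and 5 in spn-E.

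Some transcripts differed from wild type by at least 4-fold at both stages. They were 59 lower and 9 higher in aub and 60 lower and 11 higher in spn-E, and 50 of the lower ones and 2 of the higher ones were common to both mutants. Both comparisons use the same wild-type samples, and the overlap expected from that alone was not simulated for this set. The SD between the probes' changes was at most 1.20 times that of transcripts with a 4-fold stage change in wild type. This adds no evidence against variants under single probes. The value of a transcript is the median of its probes, so such variants could hardly bring it into the set. The slide was argued against, with 100% keeping a 2-fold difference within the single slide that holds both genotypes. A difference in genetic background between the wild-type stock and the mutant stocks may account for the shared part, as may variants that span all probes of a transcript, and neither was tested.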
